A study of Mus musculus with 4 samples.

How the data were processed

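Epidermis of mice labelled IL-36Ra-cKO and IL-36Ra-fl/fl was profiled by RNA sequencing, with 2 libraries per group. Per the labels' protocols, RNA was extracted from lysed tissue with Trizol, polyadenylated mRNA was enriched with oligo(dT) beads and fragmented, and cDNA libraries were amplified, circularised and sequenced as DNA nanoballs. The labels do not say whether the libraries keep the strand, so reads of a gene and an overlapping or antisense partner are not told apart. Per the submitters' processing notes, Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the mouse build GRCm39 were used, with no role or order given. The gene annotation and any filter applied before deposit are not given in the sources used here.

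The deposited table holds 4 kinds of value per library. The estimated counts per gene, per the file headers a read count, were not normalized, and 11.05% to 13.02% of the values in a library were not whole. TPM values were deposited by the authors and sum to 999999 or 1000000 in each library. FPKM values were also deposited by the authors, with sums that differ between libraries. The deposited normalized count, treated as a signal, was found to equal the count rounded up to a whole number times 1 factor per library: 1.0309 and 1.016 in the cKO-labelled libraries and 1.0802 and 0.899 in the fl/fl-labelled libraries. Those factors lie close to the inverse of median-of-ratios size factors computed here (1.0315, 1.0161, 1.0804 and 0.899), and the normalized counts were not used further. The table lists 17958 genes, of which 17838 had an identifier in the reference gene table used here and 120 did not. Of the matched genes 17718 were protein coding. The table holds 0 mitochondrially encoded genes and no Xist. The genome reference at hand is of an older mouse build than the authors' build, so it served for gene names and biotypes alone, and no coordinates are given.

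The total count per library ran from 14622791 to 16490602, and the 10 most abundant genes took 6.47% to 6.93% of them. The libraries of a group were not copies of each other, since the median gene differed by 0.267 log2 units between the cKO-labelled and 0.241 between the fl/fl-labelled libraries. Counting intervals and floors cover counting error only. A group at 0 was compared at a floor of 3 counts per library, and a group with 1 to 3 counts by its ratio with an exact binomial interval (95%).

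Each library was assigned to its group by its sample name. The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood F test with TMM scaling, the default expression filter and group as the one term. With 2 libraries per group the fit had 2 residual degrees of freedom, and 14459 genes were tested and 3499 not. The biological coefficient of variation was 0.269 and the prior degrees of freedom 2.79. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are TMM-scaled. In all, 37 gene lists (signalling, cell type, keratinocyte and technical) had been fixed before the data were examined, as had the test, the named-gene rule and the first group of alternatives described here. Lists with at least 4 tested members, 35 in all, were tested on log2 CPM (prior count 2) with camera at a preset correlation between genes of 0.01, adjusted over the lists. The mitochondrially encoded list had 0 genes in the table and the B and plasma cell list 1 tested member. Members of each list were also adjusted over the list alone.

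Genes were named by a rule in 3 parts. The targeted gene, the IL-36 genes and their receptor chains were always named. Next came up to 12 genes per direction with the largest fitted change past the threshold, with a mean of at least 1 CPM in the higher group, no overlap between the groups and an established symbol, or, where fewer than 6 passed, the 6 with the smallest p as values. Last came up to 4 members per list with the smallest p among those that passed, or the member with the smallest p as a value. After the values were seen, passing in that last part was read as passing adjusted over the list alone, because outside the sex-linked genes no member passed over all genes. In all the rule selected 102 genes, of which 1 is not reported here. Genes outside it are said to have been chosen after their values were seen.

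The alternatives set out beforehand were DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with at least 1 TPM in at least 2 libraries, median-of-ratios, upper-quartile and no scaling factors, no filter, a filter of at least 10 counts in every library of a group, other thresholds, the replicate number as a block, each library left out in turn, and genes of muscle, fat, dermis, hair follicle and blood left out. The alternative set out for FPKM or TPM was run on TPM. For the lists they included an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Added after seeing the data were robust edgeR, an adjusted p under 0.10, Y-linked genes left out, crossed replicate numbers as a block, and removal of each library's trend on effective transcript length. That length was derived from the deposited counts and FPKM, and the trend was removed through offsets from a natural spline with 5 degrees of freedom, on 13949 genes. With 1 library of a group left out, the lone library is assumed to vary like the other group, on 1 residual degree of freedom.

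The scripts were tested on simulated data for this comparison, with counts for 14459 genes, 50 genes changed at each of 4 sizes and the other 14259 unchanged. With a gene-to-gene spread as wide as in the data, edgeR recovered 0 of 50 genes at each of 2-, 4-, 8- and 16-fold, although 27, 46, 48 and 49 of them had an unadjusted p under 0.05. With the same spread for all genes of one level it recovered 13, 48, 50 and 50 of 50. In simulated lists camera called the shifted list (adjusted p = 3.27e-13) and 0 of 19 unshifted lists. Genes were drawn independently there, whereas estimated correlations in the data reached 0.907 for hair follicle and 0.983 for skeletal muscle genes. The simulation therefore gives no rate of false calls for lists whose genes vary together. A simulated length slope of -0.301 was reduced to -0.007 by the removal.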

Results

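RNA from mouse epidermis was sequenced in 4 libraries, 2 labelled IL-36Ra-cKO and 2 labelled IL-36Ra-fl/fl. IL-36Ra is the IL-36 receptor antagonist, a secreted protein encoded by Il36rn that keeps IL-36 cytokines from signalling through their receptor. The fl/fl mice carry floxed alleles, the usual control for a conditional knockout (cKO). The series title concerns aged skin, IL-36 receptor signalling and experimental osteoarthritis, and the design compares the epidermis of both genotypes. The labels give neither the age nor the sex of the mice, and the genotype field calls the first group a knockdown where the sample names say cKO. Y-linked transcripts were high only in the cKO-labelled libraries. An apparent difference in sex therefore went with the genotype label, and the 2 cannot be told apart in any difference given below. Total counts were 14723409 and 14622791 in the cKO-labelled libraries (replicates 1 and 2) and 15918854 and 16490602 in the fl/fl-labelled libraries. Nothing in the labels says that the libraries of a group came from separate animals. P-values of single genes therefore measure only the spread between these samples, which may be technical. List p-values from camera at the preset correlation rest instead on the spread over genes, which are not independent replicates.

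Across genes, which are not independent replicates, log2 CPM correlated at 0.978 between the fl/fl-labelled libraries and at 0.934 between the cKO-labelled libraries. cKO replicate 1 lay as close to fl/fl replicate 2 (r = 0.939) as to cKO replicate 2. The first principal component held 74.3% of the variance and placed cKO replicate 2 at -93.5, cKO replicate 1 at -23.4, and the fl/fl-labelled libraries at 64.7 and 52.2.

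The targeted gene was examined first. Il1f5, the older symbol of Il36rn used in the deposited table, was not lost in the cKO-labelled libraries. It had 3258 and 2508 counts in the cKO-labelled libraries and 3743 and 3489 in the fl/fl-labelled libraries, which is 193.5 ± 39.7 against 229 ± 36.2 CPM (SD, n = 2 libraries per group). The log2 fold change, cKO minus fl/fl here and throughout, was -0.24 ± 0.24 (SE, adjusted p = 0.509), and the 95% interval of the fold ran from 0.545 to 1.31. Counts per gene do not show which exons were read, and the labels do not say which part of the gene was to be deleted, so every direction given here is between libraries as labelled.

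The 3 IL-36 agonists and their receptor also gave no difference past the threshold. Il1f8 (IL-36 beta) stood at 25.5 ± 6.61 CPM in the cKO-labelled and 43.0 ± 12.6 CPM in the fl/fl-labelled libraries (SD, n = 2, adjusted p = 0.163). Il1f6 (IL-36 alpha) was at 52.9 ± 4.27 against 49.2 ± 8.74 CPM and Il1f9 (IL-36 gamma) at 199.8 ± 16.7 against 183 ± 28.1 CPM. The receptor chain Il1rl2 was at 154 ± 25.7 against 151 ± 1.37 CPM, and its partner Il1rap at 45.7 ± 7.49 against 65.8 ± 27.5 CPM. No direction is given for Il1f6, Il1f9 and Il1rl2, since the fitted fold change of Il1rl2 turned negative with median-of-ratios factors and on TPM, and those of Il1f6 and Il1f9 on TPM and with the length trend removed. Among the 9 IL-1 and IL-36 family ligands tested, none passed over all genes or adjusted over the list alone, the median log2 fold change was -0.43, and the list test gave an adjusted p of 0.521. The member with the smallest p was Il1f10, the ligand IL-38, at 0.90 ± 0.27 (SE).

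**Figure D1:**
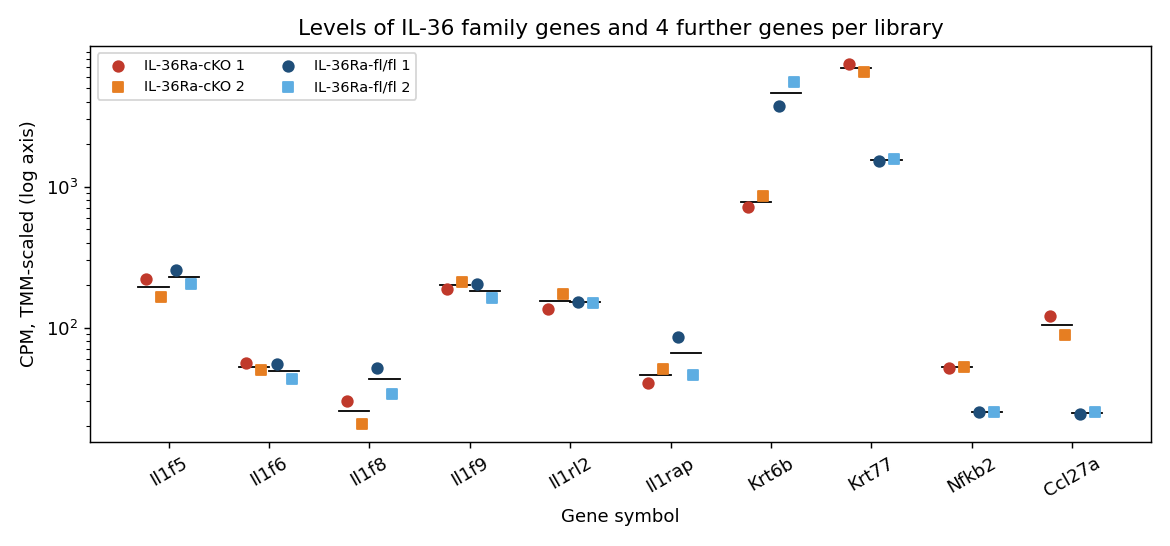
Levels of 10 genes in the 4 libraries, as TMM-scaled CPM on a log axis; each point is 1 library and each bar the mean of the 2 libraries of a group. Il1f5 and the IL-36 genes overlap or nearly overlap between the groups, whereas Krt6b lies lower and Krt77, Nfkb2 and Ccl27a lie higher in both cKO-labelled libraries.

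The cKO-labelled libraries had lower levels of the stress keratins Krt6a, Krt6b and Krt16 and higher levels of NF-kB feedback genes and of T cell genes. Genes of dermis, fat and muscle were also read, so the samples may not have been epidermis alone. Dermal fibroblast and matrix genes had medians of 5.72 to 6.46 log2 CPM in the 4 libraries. Skeletal muscle genes had a median of 3.44 in cKO replicate 2 and -1.15 in cKO replicate 1, as log2 CPM minus the fl/fl mean. Whether differing shares of these tissues set any difference given here was not tested. Of 35 gene lists tested with camera, 7 were higher as a whole: NF-kB feedback and targets, T cell, interferon gamma response and antigen presentation, immediate early and heat shock, nuclear respiratory chain, ribosomal protein, and sex-linked genes. The 6 lower lists were stress keratins and small proline-rich proteins, hair follicle and hair shaft, melanocyte, cell cycle, senescence and secretory phenotype, and proteases and inhibitors. None of these 13 calls held when the correlation between genes was estimated from the 4 libraries, with adjusted p values of 0.841 or 0.963 given with each list. That setting rests on the 2 residual degrees of freedom and called 0 of the 35 lists, also not the sex-linked list (adjusted p = 0.841). T cell and cell cycle genes lost their calls there although their estimated correlations, 0.004 and -0.004, lay under the preset 0.01. A call lost in that setting is therefore not by itself evidence of correlation between genes. For the other called lists the estimates ran from 0.067 (NF-kB feedback and targets) to 0.945 (melanocyte), above the preset. If such correlations are real, the adjusted p values of those lists at the preset are too small. Outside the sex-linked genes, no list member passed over all 14459 genes tested, so the member counts given for each list are those adjusted over the list alone, beside 0 over all genes. Among all genes tested, 2391 were higher and 2250 lower at an unadjusted p under 0.05 (edgeR). Members on both sides of a list therefore do not by themselves set that list apart from other genes.

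NF-kB feedback genes were higher together. All 17 tested members had positive log2 fold changes, with a median of 0.63, and 6 were higher adjusted over the list alone. Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, was at 1.52 ± 0.29 (SE), its relative Nfkbie at 1.79 ± 0.26, and the NF-kB subunits Nfkb2 and Relb at 1.05 ± 0.14 and 1.25 ± 0.20. The list was called at an adjusted p of 3.93e-04, with an adjusted p = 0.841 with an estimated correlation. Immediate early and heat shock genes were higher in the same libraries (library medians 1.17 in cKO replicate 1 and 0.40 in cKO replicate 2), and Nfkbia stood at 205 and 127 CPM there.

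Inflammatory mediators went both ways, as genes did as a whole. In the list of IL-36 and IL-17 responses of keratinocytes, 3 of 26 tested members were higher and 5 lower adjusted over the list alone, and the median was -0.63. Tnf was higher (2.61 ± 0.35 SE), whereas Il6 (-4.19 ± 0.63, and -3.41 without fl/fl replicate 2) and the stefin gene Stfa2 (-1.63 ± 0.17) were lower. The neutrophil attractant Cxcl5 had 1 count in the cKO-labelled and 589 in the fl/fl-labelled libraries, a ratio of 551 in favour of fl/fl (95% counting interval 98.5 to 21800). Its fl/fl counts were 153 and 436, and its log2 fold change of -8.75 was -7.87 without cKO replicate 2. It was -9.26 without fl/fl replicate 1 and -7.97 without fl/fl replicate 2. Without cKO replicate 1 the remaining cKO-labelled library had 0 counts, so no size is given. The list as a whole was not called (adjusted p = 0.113), but it was called lower with no filter (0.0442), without cKO replicate 2 (5.96e-03), without fl/fl replicate 1 (3.98e-05) and once the trend on transcript length was removed (6.50e-03). It was not called without cKO replicate 1 (0.199), without fl/fl replicate 2 (0.784) or with an estimated correlation, at an adjusted p of 0.963 and, with the length trend removed, 0.815.

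Among 24 chemokines tested, 6 were higher and 2 lower adjusted over the list alone. Ccl27a, which draws T cells to skin, stood at 104 ± 21.8 against 24.9 ± 0.516 CPM (SD, n = 2; log2 fold change 2.07 ± 0.20 SE). Xcl1 and Ccl21a were higher by 2.83 ± 0.47 and 1.80 ± 0.33 on the log2 scale, and Xcl1 by 3.51 without fl/fl replicate 2. The list had a median of -0.42 and was not called (adjusted p = 0.910). Of 23 further cytokines and growth factors, 2 were higher and 3 lower adjusted over the list alone, with a median of -0.26 and an adjusted p of 0.509 for the list. Il34, the Langerhans cell survival factor made by keratinocytes, was higher at 2.04 ± 0.17, and the growth factor Tgfa was lower at -1.04 ± 0.20. Among 15 IL-1 and IL-36 receptors and adaptors, the decoy receptor Il1r2 (1.74 ± 0.17) and the inhibitory receptor Sigirr (1.80 ± 0.29) were higher and the IL-33 receptor Il1rl1 (-3.36 ± 0.76, from -4.03 without cKO replicate 1 to -2.29 without fl/fl replicate 2) lower adjusted over the list alone. That list's median was -0.015, its mean 0.018, its test direction upward, and its adjusted p 0.670.

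T cell and antigen presentation genes were higher in both cKO-labelled libraries. Of 12 T cell genes tested, 8 were higher adjusted over the list alone and the list median was 1.32, with library medians of 1.24 and 1.25 above the fl/fl mean. The chains of the T cell receptor complex Cd3g (24.4 ± 2.22 against 7.61 ± 0.477 CPM, SD, n = 2), Cd3e and Cd247 had log2 fold changes of 1.68 ± 0.20, 1.54 ± 0.31 and 1.88 ± 0.29, and the interleukin receptor chain Il2rb had 2.01 ± 0.40 (SE). The list was called at an adjusted p of 7.45e-04, with an adjusted p = 0.841 with an estimated correlation. Of 29 genes of the interferon gamma response and antigen presentation, 11 were higher adjusted over the list alone, with a median of 0.65. They included the class I gene H2-Q7 (1.76 ± 0.21), the immunoproteasome subunits Psmb8 (1.24 ± 0.20) and Psmb9 (1.17 ± 0.19) and the peptide transporter Tap2 (0.95 ± 0.15). That list was also called at an adjusted p of 7.45e-04, with an adjusted p = 0.963 with an estimated correlation.

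Other leukocyte lists were not called with TMM scaling and the default filter on all 4 libraries. Among 25 macrophage, dendritic and Langerhans cell genes, 8 were higher and 0 lower adjusted over the list alone, with a median of 0.22 and an adjusted p of 0.0724 for the list, which was called higher on log2(TPM + 1) (0.0219), with no filter (0.0442), without cKO replicate 1 (0.041) and without fl/fl replicate 2 (4.45e-04). It was not called without cKO replicate 2 (0.202), without fl/fl replicate 1 (0.805), with an estimated correlation (0.963) or with the length trend removed (0.312). Ciita, the class II master regulator, was at 2.01 ± 0.21 (SE), the class II genes H2-Eb1 and H2-Ab1 at 1.26 ± 0.21 and 1.34 ± 0.23, and the dendritic cell lectin Mgl2 at 1.83 ± 0.28. Of 29 type I interferon response genes, none passed adjusted over the list alone, and the list had a median of 0.21 and an adjusted p of 0.851, but was called higher without cKO replicate 1 (adjusted p = 0.0452). The test direction was downward without cKO replicate 2 (0.195), without fl/fl replicate 1 (0.824) and with the length trend removed (0.958), and the library medians were -0.28 in cKO replicate 1 and 0.30 in cKO replicate 2. Usp18, its member with the smallest p, was at 1.86 ± 0.46, and at 2.60 without fl/fl replicate 2. Among 9 neutrophil genes tested, Il1r2 was higher and Hdc (-2.44 ± 0.48) and Clec4d (-3.92 ± 0.79, from -5.18 without cKO replicate 1 to -3.24 without fl/fl replicate 2) lower adjusted over the list alone, with a median of -0.25 and an adjusted p of 0.521 for the list, which was called lower without fl/fl replicate 1 (adjusted p = 3.85e-04) but had an upward direction without fl/fl replicate 2 (0.921).

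Stress keratins and small proline-rich proteins were lower. These genes are low in resting epidermis, high in wounded or inflamed epidermis, and some are also expressed in hair follicles. Krt6b stood at 782 ± 96.6 against 4623 ± 1230 CPM (SD, n = 2) and Krt16 at 1284 ± 28.7 against 3711 ± 631 CPM, with log2 fold changes of -2.56 ± 0.31 and -1.53 ± 0.25 (SE). Krt6a gave -2.52 ± 0.32, although reads of Krt6a and Krt6b are hard to tell apart, and Sprr1b gave -2.01 ± 0.28. Of 15 members tested, 6 were lower adjusted over the list alone, and the median was -1.42. The list was called at an adjusted p of 3.83e-05, with an adjusted p = 0.963 with an estimated correlation, and hair follicle genes were lower in the same libraries (list median -3.0).

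Differentiation genes split, as genes did as a whole. Of 53 cornified envelope and late differentiation genes, 6 were higher and 5 lower adjusted over the list alone. Krt77, a suprabasal keratin, was at 6972 ± 620 against 1544 ± 38.9 CPM (SD, n = 2; log2 fold change 2.18 ± 0.25 SE), and Lor, the main cornified envelope protein, at 1476 ± 656 against 346 ± 13.7 CPM (2.09 ± 0.38). Sbsn and Lce1m were higher by 1.4 ± 0.25 and 2.76 ± 0.46, Lce1m by 2.02 without cKO replicate 1. The 5 lower members, named after their values were seen, were Lce3a (-3.76), Rptn (-3.03), Lce3f (-2.58), Lce3b (-2.46) and Tgm3 (-1.31). The list median was 0.42, the mean 0.01 and the adjusted p 0.452. Its library medians were 0.76 in cKO replicate 1 and -0.11 in cKO replicate 2, and it was called higher without cKO replicate 2 (adjusted p = 2.43e-03) and lay in the other direction without cKO replicate 1 (0.516). Among 29 barrier lipid genes, 5 were higher and 3 lower adjusted over the list alone, with a median of 0.01 and an adjusted p of 0.868. The lipoxygenases Aloxe3 (1.46 ± 0.19) and Alox12e (1.39 ± 0.19) and the ceramide synthesis gene Sptlc3 (1.20 ± 0.20) were higher, and the sphingomyelin synthase Sgms2 (-1.95 ± 0.28) was lower. Of 18 basal keratinocyte genes, Krt15 (1.62 ± 0.28) and Col7a1 (0.86 ± 0.18) were higher and 3 were lower adjusted over the list alone, among them Itgb1 (-1.04 ± 0.23) and Cdh3 (-0.78 ± 0.17). That list had a median of -0.04, a test direction upward, and an adjusted p of 0.910.

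Cell cycle genes were lower. Of 32 members, 31 had negative log2 fold changes, with a median of -0.59, and 18 were lower adjusted over the list alone. The mitotic motors Kif11 and Cenpe (-1.08 ± 0.15 and -1.07 ± 0.15 SE), the topoisomerase Top2a (-1.03 ± 0.18) and cyclin B1, Ccnb1 (-1.07 ± 0.20), led them. The list was called at an adjusted p of 4.24e-07, with an adjusted p = 0.841 with an estimated correlation. Hair follicle genes were lower in the same libraries, with library medians of -1.97 and -8.90, against -0.52 and -0.66 for the cell cycle genes.

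The senescence and secretory phenotype list and the list of proteases and inhibitors were lower on balance. Mmp13, a collagenase, stood at 2.11 ± 0.472 against 40.0 ± 19.1 CPM (SD, n = 2; log2 fold change -4.24 ± 0.46 SE). In the senescence and secretory phenotype list, 5 of 27 tested members were lower and 1 higher adjusted over the list alone, with a median of -0.61. The lower ones included Mmp13, Il6 and Lmnb1 (-1.20 ± 0.23), a lamin whose loss accompanies senescence, and the higher one was Igfbp3 (1.18 ± 0.22). Among 36 proteases and inhibitors, 10 were lower and 1 higher adjusted over the list alone, with a median of -0.40. The aggrecanase Adamts5 (-1.76 ± 0.24) and the inhibitor Timp3 (-1.05 ± 0.17) were lower, and the kallikrein Klk11 (0.92 ± 0.16) was higher. Both lists were called, at adjusted p values of 0.0343 and 0.0211, each with an adjusted p = 0.963 with an estimated correlation. The secretory list was not called without cKO replicate 1 (adjusted p = 0.126) or fl/fl replicate 2 (0.242), nor the protease list without cKO replicate 2 (0.0573) or fl/fl replicate 2 (0.282).

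Hair follicle and pigment cell genes were lower, to very different extents in both cKO-labelled libraries. All 48 hair follicle and hair shaft genes had negative log2 fold changes, with a median of -3.0. The library medians against the fl/fl mean were -1.97 in cKO replicate 1 and -8.90 in cKO replicate 2. The latter is set in part by the prior count of 2, since the list lay at -2.35 log2 CPM there, near the floor. Dsc2, a desmosomal cadherin, was lower at -3.31 ± 0.30 (SE), and the hair keratin-associated gene Krtap9-1 had 1 count in the cKO-labelled and 114 in the fl/fl-labelled libraries, a ratio of 107 in favour of fl/fl (95% counting interval 18.8 to 4250). Its log2 fold change of -6.43 was -5.56 without cKO replicate 2. Without cKO replicate 1 the remaining cKO-labelled library had 0 Krtap9-1 counts, so no size is given. Dsc2 and Krtap9-1 were the 2 members that passed adjusted over the list alone. All 10 melanocyte genes were negative, with a median of -2.12 and library medians of -1.14 and -5.52. Mitf, the melanocyte transcription factor, was the 1 member lower adjusted over the list alone (-2.07 ± 0.25). The lists were called at adjusted p values of 1.14e-09 and 7.07e-03, each with an adjusted p = 0.963 with an estimated correlation. Skeletal muscle genes also set cKO replicate 2 apart, with a library median of 3.44 against -1.15 in cKO replicate 1. That list of 24 genes had a median of 2.55 and an adjusted p of 0.338, and none passed adjusted over the list alone. It was called higher without cKO replicate 1 (adjusted p = 1.14e-15) and lower without cKO replicate 2 (9.71e-06). Myh4, its member with the smallest p, was at -1.02 ± 0.23.

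**Figure D2:**
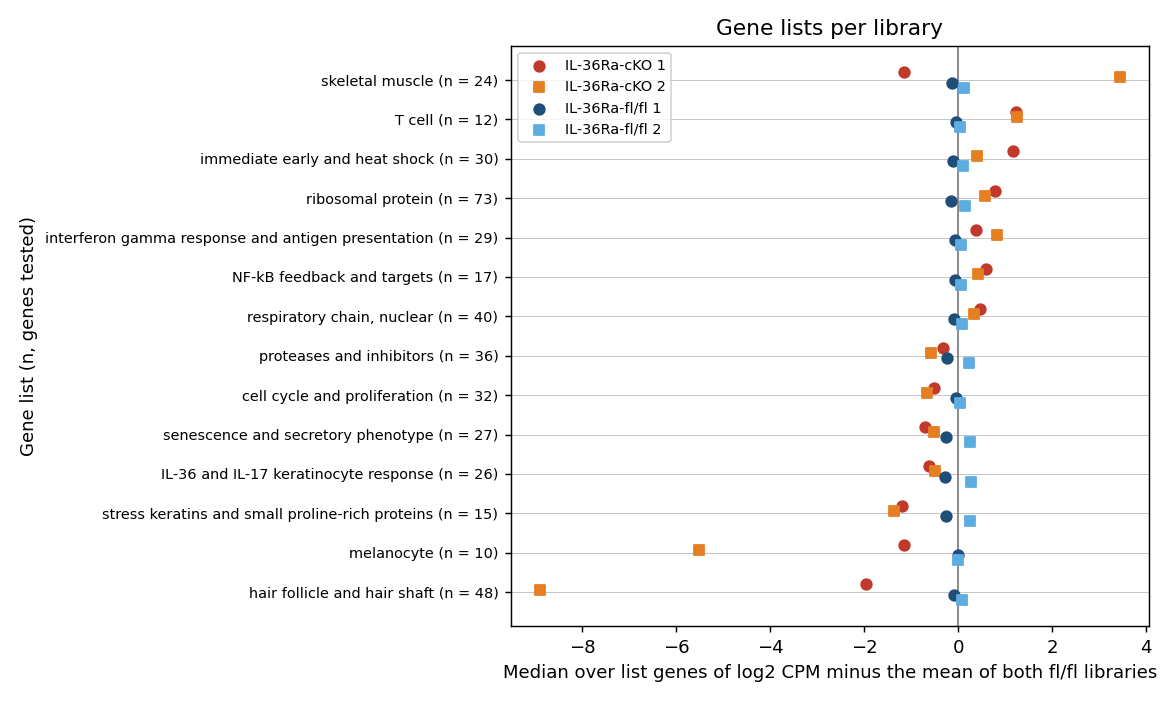
Medians of 14 gene lists in each library, as log2 CPM minus the mean of both fl/fl-labelled libraries; each point is 1 library and n is the number of genes tested. T cell genes lie at 1.24 and 1.25 in the cKO-labelled libraries, and hair follicle genes at -1.97 and -8.90.

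Immediate early and heat shock genes were higher, more so in cKO replicate 1 (library median 1.17) than in cKO replicate 2 (0.40). Of 30 tested, 3 were higher adjusted over the list alone, with a median of 0.81. They were the chaperones Hspa1a (1.59 ± 0.18 SE) and Hspb1 (1.77 ± 0.30) and the phosphatase Dusp1 (1.47 ± 0.28). The list was called at an adjusted p of 7.45e-04, with an adjusted p = 0.963 with an estimated correlation, and was not called without cKO replicate 1 (adjusted p = 0.0653).

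Genes with short transcripts were higher as a class. All 73 ribosomal protein genes had positive log2 fold changes, with a median of 0.69, and the list was called at an adjusted p of 1.04e-13. Of 40 nuclear respiratory chain genes, 34 were positive, with a median of 0.42 and an adjusted p of 7.45e-04. Both had an adjusted p = 0.963 with an estimated correlation, and no member of either passed adjusted over the list alone. Their members with the smallest p were Rplp1 (1.28 ± 0.26 SE) and Ndufa5 (0.91 ± 0.19). Across all genes the median log2 fold change went from 0.41 in the tenth with the shortest transcripts (median 582 nt) to -0.39 in the tenth with the longest (7210 nt), and fold changes between libraries of the same group also followed length. With each library's trend on transcript length removed, an alternative chosen after seeing the data, the ribosomal median was 0.30 and the list was called at an adjusted p of 4.36e-06, but not with an estimated correlation (adjusted p = 0.815). The respiratory chain median was then 0.05 and the list was no longer called (adjusted p = 0.958).

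**Figure D3:**
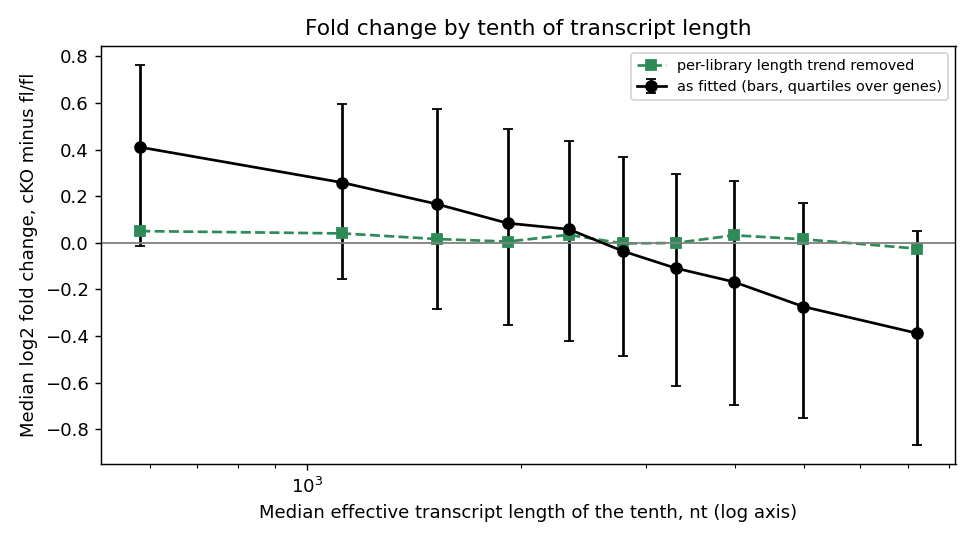
Median log2 fold change, cKO minus fl/fl, in 10 classes of genes of equal size ordered by transcript length (log axis, nt), as fitted (solid line, bars spanning the quartiles over genes) and with the trend of each library removed (dashed line). The fitted medians go from 0.41 to -0.39, and those after removal stay between -0.03 and 0.05.

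At the level of single genes, 4 were higher and 0 lower over all 14459 tested (edgeR quasi-likelihood, adjusted p under 0.05). They were the Y-linked genes Ddx3y, Uty and Eif2s3y (each adjusted p = 0.0221) and the major urinary protein gene Mup22 (adjusted p = 0.0316). Ddx3y, Uty and the Y-linked Kdm5d were present in both cKO-labelled libraries and at or near 0 in both fl/fl-labelled libraries, where Eif2s3y had 3.53 and 4.60 CPM against 123 and 136 CPM, so high levels of Y-linked transcripts went with the genotype label. Uty had a log2 fold change of 7.61 ± 0.31 (SE) and Eif2s3y, which resembles its X-linked relative Eif2s3x, 4.99 ± 0.22. Ddx3y had 3577 counts against 1, a ratio of 3820 (95% counting interval 686 to 151000), and a log2 fold change of 10.82 without fl/fl replicate 1. Without fl/fl replicate 2 the remaining fl/fl-labelled library had 0 counts, so no size is given. Mup22 was at least 1660-fold and Kdm5d (adjusted p = 0.0634) at least 175-fold higher than a floor of 3 counts per library, and major urinary protein genes are near-identical copies that can share reads. All 4 sex-linked genes tested passed adjusted over the list alone, and the list, with a median log2 fold change of 7.53 when Kdm5d is set to its floor, was called at an adjusted p of 7.66e-07, with an adjusted p = 0.841 with an estimated correlation. The next gene higher was Cfap57 (3.08 ± 0.20, adjusted p = 0.0634). The genes with the smallest p among those lower were Spp1, which encodes osteopontin (-2.57 ± 0.20), the growth factor Nrg1 (-2.64 ± 0.23), Slco5a1 (-2.88 ± 0.26), Dsc2, Itih5 (-1.89 ± 0.18) and the olfactory receptor gene Olfr1033 (-2.14 ± 0.20), each at an adjusted p of 0.0656.

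The low count of calls came with many small p values. At an unadjusted p under 0.05, 2391 genes were higher and 2250 lower, and at an adjusted p under 0.10, a threshold added after seeing the data, 1234 were higher and 967 lower. DESeq2 called 1146 genes higher and 1428 lower (44.5% higher), limma-voom 4 and 0, and limma-trend on log2(TPM + 1) 4 and 1. With upper-quartile factors edgeR called 236 higher and 152 lower (60.8% higher), and with library size only 634 and 725 (46.7%), against 100% higher with TMM. Without cKO replicate 1 the counts were 308 and 579, and without cKO replicate 2 or either fl/fl-labelled library they were 0 and 0. Without the Y-linked genes they were also 0 and 0, since Mup22 then had an adjusted p of 0.0678.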

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

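The test of the length trend on respiratory chain genes and the test of genotype alone were chosen only after the result was seen.

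Counts and FPKM in the deposited table imply an effective transcript length for each gene in each library, and this unused quantity differed between libraries. Against fl/fl replicate 1, genes with short transcripts had effective lengths larger by 65.2 nt in cKO replicate 1 and by 20.5 nt in cKO replicate 2, against -2.7 nt in fl/fl replicate 2. Over all 6392 genes with enough reads the median shifts were 65.1 and 20.2 nt in cKO replicates 1 and 2. The shift was thus not particular to short transcripts. Under RSEM's definition a larger effective length goes with a shorter mean fragment.

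Ribosomal protein and respiratory chain genes, which have short transcripts, were higher in the cKO-labelled libraries, and log2 fold changes fell with transcript length across genes (Spearman -0.298 over 13949 genes, which are not independent), although a length trend was also present within both groups (0.328 for fl/fl replicate 1 minus 2 and -0.186 for cKO replicate 1 minus 2). A length trend between libraries may account for the respiratory chain genes, whose median kept 11.6% of its size after the trend was removed (0.42 before, 0.05 after). For the ribosomal protein genes it cannot be told apart from a change in these genes themselves, since 44.1% of the median was left, between the bounds set for either reading. Genotype alone also stays open, since the ribosomal median differed by 0.26 log2 units between cKO replicates 1 and 2 and by 0.29 between fl/fl replicates 2 and 1, less than the 0.69 between the groups, and sex went with genotype. What set the length trend was not tested.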

How the results depend on the processing

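Robust edgeR, an adjusted p under 0.10, Y-linked genes left out, crossed replicate numbers and removal of the length trend were chosen only after the result was seen; the cause of each change was not tested unless stated.

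The count of genes depended on the test and the scaling. Against 4 higher and 0 lower, the counts were 1146 and 1428 with DESeq2, 634 and 725 with library size only, 236 and 152 with upper-quartile factors, 4 and 1 on log2(TPM + 1), and 1234 and 967 at an adjusted p under 0.10. They were 0 and 0 with Y-linked genes left out, with crossed replicate numbers as a block, and at an adjusted p under 0.01. Leaving out 1 library gave 0 to 308 higher and 0 to 579 lower, with calls only without cKO replicate 1. limma-voom, log2(TPM + 0.1), robust edgeR, the strict filter, removal of the length trend and a 2-fold minimum gave 4 and 0, median-of-ratios factors 3 and 0, and no filter or leaving out muscle, fat, dermis, hair and blood genes 6 and 0. The TPM settings moved the median of all genes by -0.157 (+ 1) and -0.175 (+ 0.1). The replicate numbers are shared, but the labels give no pairing, and deviations of libraries with the same number correlated at -0.13; the replicate block gave 4 and 0 genes and 8 and 6 lists, adding skeletal muscle as higher (adjusted p = 0.0454), a list called higher without cKO replicate 1 (1.14e-15) and lower without cKO replicate 2 (9.71e-06). Crossed numbers gave 0 and 0 genes and 7 and 6 lists. The Il1f5 log2 fold change stayed negative and not past the threshold, from -0.47 to -0.05 with 1 library left out.

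For lists, against 7 higher and 6 lower, an estimated correlation, tested on 2 residual degrees of freedom, gave 0 and 0. With fry the counts were 2 and 1, keeping T cell (adjusted p = 0.0389), sex-linked and cell cycle (both 0.00996). Leaving out 1 library gave 7 to 9 higher and 4 to 10 lower, the most without fl/fl replicate 1. None of these 13 lists changed direction in any setting. On log2(TPM + 1) respiratory chain (adjusted p = 0.0635), secretory (0.0781) and protease (0.0706) lists were no longer called, and the macrophage, dendritic and Langerhans cell list was (0.0219).

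Of 102 named genes, 4 changed sign, none past the threshold. Il1f6 was -0.262 with the length trend removed, -0.145 on log2(TPM + 0.1), -0.144 on log2(TPM + 1) and -0.0869 to 0.295 with 1 library left out. Il1f9 was -0.0493, -0.0659, -0.0656 and -0.0391 to 0.292 in the same order. Il1rl2 was -0.00641 with DESeq2, -0.00574 with median-of-ratios factors, -0.12 in both TPM settings and -0.15 to 0.19 with 1 library left out. Jchain was -1.24 to 0.0439 with 1 library left out. Of the 1928 values of named genes under alternatives, 266 gained and 22 lost the threshold. Depth left 3499 genes too low to test. At the depth and spread of these libraries the simulation recovered 0 of 50 genes changed 16-fold, although 49 had an unadjusted p under 0.05. It left 14259 genes unchanged, whereas 4641 genes in the data had an unadjusted p under 0.05. The adjustment is stricter where few genes change, so that 0 does not measure the power of this comparison.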

Other observations

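The tests of sex, of genotype alone and of follicle tissue as the whole cause were chosen only after the result was seen, and the liver and permanent follicle genes after the leading differences but before their own values were seen.

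Clock and antioxidant genes went both ways, as genes did as a whole. Of 18 circadian clock genes, 3 were higher and 3 lower adjusted over the list alone. The clock activators Npas2 (2.72 ± 0.26 SE) and Arntl (0.88 ± 0.16) were among the higher, and the repressor Nr1d1 (-1.36 ± 0.21) was among the lower. The median was -0.32, the mean -0.03 and the adjusted p of the list 0.847. That test looks for 1 direction and cannot register members that move apart. The fry test for changes in either direction gave an unadjusted p of 1.3e-04, but also 1.5e-04 for basal keratinocyte genes. Of 27 antioxidant genes, 5 were higher and 6 lower adjusted over the list alone. The glutathione transferases Gsta3 (4.14 ± 0.34) and Gsta2 (2.56 ± 0.33) were higher, and Gclc (-0.98 ± 0.15) and Gclm (-1.17 ± 0.20), which make glutathione, were lower. That list had a mean of 0.01, a test direction downward and an adjusted p of 0.868. Of 23 unfolded protein response genes (median 0.18, adjusted p = 0.452) and 23 cholesterol synthesis genes (-0.32, 0.343) none passed adjusted over the list alone, and the members with the smallest p were Herpud1 (0.93 ± 0.16) and Stard4 (-0.88 ± 0.23).

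Markers of other skin cells were not called as lists with all 4 libraries. Of 21 sebaceous gland genes, the acyl-CoA synthetase Acsbg1 (1.26 ± 0.18 SE) and the triglyceride synthesis gene Dgat2 (1.07 ± 0.20) were higher and Cyp2g1 (-5.74 ± 0.95, from -9.38 without cKO replicate 1 to -4.79 without cKO replicate 2) lower adjusted over the list alone, with a median of -0.34 and an adjusted p of 0.452. Each of 5 further lists had 1 such member. It was Pdgfra (-1.73 ± 0.28) of 24 dermal fibroblast and matrix genes (median -0.14, adjusted p = 0.829), Thrsp (3.47 ± 0.62, from 2.82 without fl/fl replicate 1 to 4.70 without fl/fl replicate 2) of 17 adipocyte genes (0.34, 0.343) and Cldn5 (2.16 ± 0.38) of 13 endothelial genes (0.13, 0.847). It was Hdc (-2.44 ± 0.48) of 11 mast cell genes (-0.44, 0.173) and Slc4a1 (-3.69 ± 0.71, from -5.60 without cKO replicate 1 to -2.89 without cKO replicate 2) of 8 red blood cell genes (0.96, 0.868). With 1 library left out, the sebaceous (adjusted p = 5.46e-05) and cholesterol synthesis (0.0219) lists were called lower without cKO replicate 1, the adipocyte list higher without fl/fl replicate 2 (6.09e-05) and the dermal list lower without fl/fl replicate 1 (0.0147). The mast cell list was called lower without cKO replicate 2 (0.0154) and without fl/fl replicate 1 (0.0159). The direction was the opposite for the sebaceous (0.213) and cholesterol synthesis (0.734) lists without cKO replicate 2, the adipocyte list without fl/fl replicate 1 (0.713) and the dermal list without fl/fl replicate 2 (0.282). Library medians of red blood cell genes were -0.23 in cKO replicate 1 and 1.34 in cKO replicate 2. Of the B and plasma cell list only Jchain was tested (-0.71 ± 0.51, adjusted p = 0.368, and 0.04 without fl/fl replicate 1).

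Y-linked genes and Mup22 led the differences. Liver RNA in the cKO-labelled libraries is argued against, because 12 abundant liver transcripts had a median of 0.502 CPM there, with Alb at 4.90 and 2.64 CPM, while Mup22 lay at 341 and 287 CPM. Of those 12, only Alb, Trf and Hp passed the expression filter. Trf lay at 96.8 and 90.8 CPM in the cKO-labelled and 26.4 and 86.9 CPM in the fl/fl-labelled libraries. Hp lay at 147 and 105 against 76.3 and 375 CPM. A difference in the sex of the mice may account for the Y-linked genes, since 4 X-linked genes that escape inactivation had a median log2 fold change of -1.41, with Eif2s3x at 152 and 157 against 445 and 378 CPM. Whether sex or genotype set Mup22, and any other difference reported, stays open, because both went together in all 4 libraries.

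Hair follicle and melanocyte genes were lower in the cKO-labelled libraries. The hair shaft median differed by 6.93 log2 units between the cKO-labelled libraries. The prior count of 2 sets part of that size, since the list median in cKO replicate 2 was -2.35 log2 CPM, near the floor. Genotype alone, with a like effect in both libraries, thus missed its bound. The bound for genotype was set after the values were seen and cannot decide, because a genotype effect could vary between samples. The median of 10 permanent follicle genes lay 2.48 log2 units above that of the hair shaft list, more than their SD of 1.0. Less follicle tissue of every kind as the whole cause thus missed its bound. That bound cannot decide, because expression of these genes outside follicles would keep their median up and was not measured. Whether less follicle tissue contributed also stays open, because the permanent follicle genes had a median of -0.53 with members on both sides. They ran from Lgr5 at -2.24 ± 0.50 to Lgr6 at 0.88 ± 0.17 (SE), with library medians of -0.30 in cKO replicate 1 and -1.04 in cKO replicate 2. Hair cycle stage, the depth of the sampled tissue, sex and genotype could each contribute and were not told apart.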
